A study of Dictyostelium discoideum with 28 samples.

How the data were processed

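The series compared wild-type AX4 cells of the social amoeba Dictyostelium discoideum with a strain lacking gtaG, the gene of a GATA-type transcription factor, through development. Cells were grown in axenic HL5 medium, washed in a buffered salt solution (PDF) and left to develop on filters, per the labels' protocols. Libraries came from 7 times (0, 4, 8, 12, 16, 20 and 24 h) and 2 genotypes, with 2 biological replicates in each of the 14 groups, which makes 28 libraries. Per the labels' protocols, poly-A RNA was selected, fragmented and made into barcoded libraries, which were pooled 14 to a lane and sequenced as 50-base reads on an Illumina Genome Analyzer II. No lane, date or batch was named for any library.

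Each library had 2 deposited files. One held raw whole-number read counts for 12435 genes, deposited by the authors without normalization (100% of the values were whole numbers). The other held RPKM values deposited by the authors. These equalled the count divided by the library total and by a gene length, to within 1%, for 100% of the values checked, and the implied length had a median of 0.905 times the gene length in the reference table. Bowtie 0.12.7 was named in the submitters' processing notes. The genome build, the counting tool, the use of strand and the treatment of reads with several matches are not given in the sources used here. Reads of near-identical genes may therefore have been split or dropped, so genes of the actin and hssA/2C/7E families, and genes whose symbols end in -1 because the reference lists a close copy, are reported as uncertain. Symbols came from a RefSeq gene table of assembly dicty_2.7, which was used for names and gene lengths only. It matched 12304 of the 12435 identifiers, of which 3508 had a symbol of their own, and the 131 others keep their identifiers.

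Total counts ranged from 5429366 to 10385117 per library, and the 10 most abundant genes took between 5.19% and 15.2% of a library. Counting error and replicate spread together set the precision. The common biological coefficient of variation was 0.219 with 14 residual degrees of freedom. Intervals and floors (3 counts, summed over a group) cover counting error only.

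Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr (10768) were scaled by TMM and fitted with 1 mean per group over all 28 libraries, so that groups shared an estimate of the spread. Quasi-likelihood tests (glmQLFit, glmQLFTest) compared the gtaG null strain with the wild type at each time, at any time (an F test), between 16 h and 24 h within each strain, and between the strains in that late change (an interaction). An F test over wild-type times gave the genes regulated in development. All adjusted p-values for genes are from this edgeR test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are the null strain minus the wild type. CPM is the usual count per 1e6 counts of TMM-scaled library size, given as mean ± SD with n = 2. Tested on simulated data made from the real means, library sizes and spread, the 24 h test recovered 39% of genes changed by 1 on the log2 scale and 94% of those changed by 2, and 8 of its 141 calls were false (5.67%). At 8 h the same test recovered 22% and 93%, and at 16 h 30% and 95%. The simulation changed 100 genes by each size, as many up as down, and held no replicate or gene length trend. The real strains differed far more widely at 24 h, so these rates may not hold for the real tests.

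Gene lists were tested with camera (limma 3.58.1, voom values, preset correlation 0.01) at 7 times and for the late change, with Benjamini-Hochberg adjustment over 192 tests of 24 lists, and again with an estimated correlation and with fry. The lists covered prestalk and stalk markers, prespore markers, spore maturation, spore germination, terminal signalling, DIF-1 metabolism, aggregation, growth phase markers, extracellular matrix, autophagy, ribosomal proteins, proteasome, GATA, bZIP, Myb and other cell-type factors, histidine kinases, polyketide synthases, ABC transporters, cytochromes P450, the hssA/2C/7E family, actins, tgr and psi families, colossins, heat shock, cell cycle, histones, mitochondrial genes and non-coding genes. Lists with under 5 tested members had no list test. Some genes are members of several lists, so lists that share them are not separate evidence. Among these, srfA is also in the spore maturation list, and expl7 and expl2 are also among the prestalk and stalk markers. Families of 8 or more genes sharing a symbol stem were tested separately (90 families, 720 tests). Library resemblance was described by Spearman correlation over genes regulated in wild-type development. Late-induced genes were chosen in one wild-type replicate (a rise of at least 4 times from 16 h to 24 h, log2 of CPM + 1) and read in the other replicate and in the null libraries.

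The groups, tests, gene lists and most alternatives were fixed before the data were examined. Named genes were chosen by a rule fixed then: at most 12 per direction and comparison with the largest fold change among called genes with at least 20 CPM in the higher group, a symbol, no overlap between the strains' libraries, and at most 2 per family, together with gtaG and up to 4 members of each list by adjusted p. Genes without a symbol are named only where few were called, which was decided after their values were seen. The alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, total counts only, other filters and thresholds, replicate blocks, the deposited RPKM as log2(value + 1) in limma, single times, other early times and omission of each library. A per-library correction for gene length, applied to the gene and list counts, and a fit to the 16 h and 20 h libraries alone were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.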

Results

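Transcript levels were measured by poly-A RNA sequencing in developing Dictyostelium discoideum cells. The wild type (AX4) and a strain lacking gtaG were each sampled at 7 times from 0 h to 24 h after the start of starvation-induced development, with n = 2 biological replicates per strain and time. The 28 libraries held between 5429366 counts (wild type at 24 h, replicate 2) and 10385117 counts (wild type at 12 h, replicate 1), with a median of 6773250.5. Spearman correlations between the replicates of a group lay between 0.9676 and 0.9881 across genes. In 10 of the 14 groups the difference between replicates followed gene length (Spearman rho across genes from -0.739 to -0.514), and in the 4 groups of 16 h and 20 h it lay between -0.271 and 0.142. Values below are TMM-scaled CPM, mean ± SD with n = 2, and log2 fold changes are the null strain against the wild type unless stated. Genes that rose or fell, or were higher or lower, did so in the null strain against the wild type.

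The first comparison followed the gtaG transcript itself, a check of the strains' labels. In the wild type gtaG was low at 0 h (0.542 ± 0.0556 CPM, n = 2) and reached 94.3 ± 1.39 at 16 h, 156 ± 7.02 at 20 h and 104 ± 2.63 at 24 h. In the null strain it was lower from 12 h on, with 5.03 ± 3.36 against 30.1 ± 13.8 CPM at 12 h, 38.3 ± 15 at 16 h, 44.1 ± 2.35 at 20 h and 31.8 ± 2.21 at 24 h. These levels were 16.8%, 40.6%, 28.3% and 30.6% of the wild type's. By edgeR QL with BH adjustment the log2 fold changes were -2.57 at 12 h (adjusted p = 0.0029), -1.30 at 16 h (adjusted p = 0.048), -1.82 at 20 h (adjusted p = 0.0012) and -1.71 at 24 h (adjusted p = 0.0018). At 0 h and 8 h the log2 fold changes, 0.66 and -0.30, did not pass (edgeR adjusted p = 1 for each). Reads of gtaG therefore remained in every null library, with 228 and 225 raw counts at 24 h against 614 and 509 in the wild type, and which part of the gene was removed is not given in the sources used here. At 4 h gtaG went against the label: the libraries labelled null held 78 and 37 counts, and those of the wild type 10 and 3 (log2 fold change 2.82, edgeR adjusted p = 0.043). The call for gtaG at 12 h was lost without wild type 12 h replicate 2 (log2 fold change -2.02, edgeR adjusted p = 0.073) and without null 12 h replicate 1 (-2.01, edgeR adjusted p = 0.11). The call for gtaG at 4 h was lost without wild type 4 h replicate 2 (edgeR adjusted p = 0.66) and without null 4 h replicate 1 (edgeR adjusted p = 0.22). It was also lost, at edgeR adjusted p from 0.051 to 0.062, without wild type 0 h replicate 1 or any 1 of the wild-type libraries of 8, 16, 20 and 24 h or null libraries of 20 and 24 h. The call for gtaG at 16 h was lost without null 16 h replicate 2 (log2 fold change -0.947, edgeR adjusted p = 0.61), wild type 16 h replicate 1 or 2 (0.16 and 0.18) or null 16 h replicate 1 (0.052). Without any 1 of the libraries of 0, 8, 20 or 24 h its edgeR adjusted p lay between 0.05 and 0.067.

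**Figure D1:**
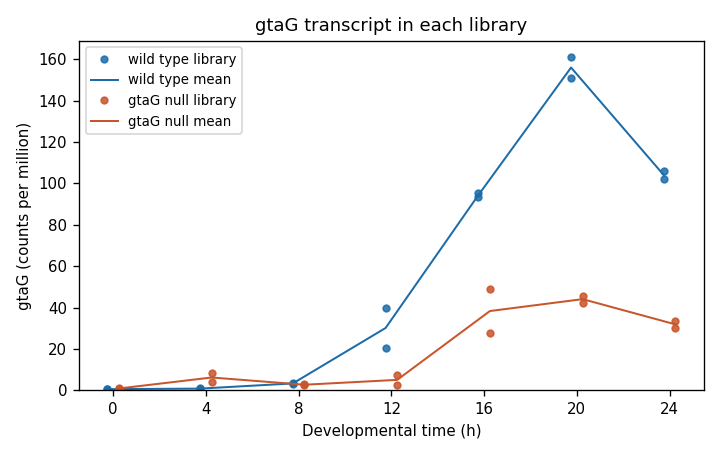
gtaG transcript (CPM) in each library against developmental time (h), with points for libraries and lines for the means of the wild type and the null strain. The null means lie below the wild-type means from 12 h on, at 44.1 against 156 CPM at 20 h, and above at 4 h.

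The strains were compared at each time to ask when their transcript levels parted. By edgeR on all libraries, without a replicate block, few genes differed up to 8 h, and between 12 h and 24 h the number increased. With TMM most of the called genes from 12 h on were lower in the null strain, but at 20 h and 24 h most were higher with total counts (31.5% and 27.6% lower) or the deposited RPKM (32.4% and 26.9% lower). The RPKM were themselves scaled by library totals, so here and below these settings are not separate evidence. Of 10768 genes tested with edgeR QL, 4 differed at 0 h, 17 at 4 h, 4 at 8 h, 52 at 12 h, 394 at 16 h, 1674 at 20 h and 2265 at 24 h. An F test over all times called 2253 genes. The counts at 4 h and 12 h depended on the method, with 191 and 234 genes by DESeq2 and 88 and 210 after a correction for gene length. With replicate number as an additive block edgeR called 210 and 273. At unadjusted p under 0.05 the counts were 466, 1003, 383, 1190, 1300, 2935 and 3563 in the same order. Of the genes lower at 20 h, 749 were also lower at 24 h (155 expected by chance, from different libraries). The higher genes of 20 h and 24 h shared 245 (39.1 expected). Of the 51 genes lower at 12 h, 31 were also lower at 16 h (1.72 expected). In wild-type development 9918 genes changed (92.1%).

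**Figure D2:**
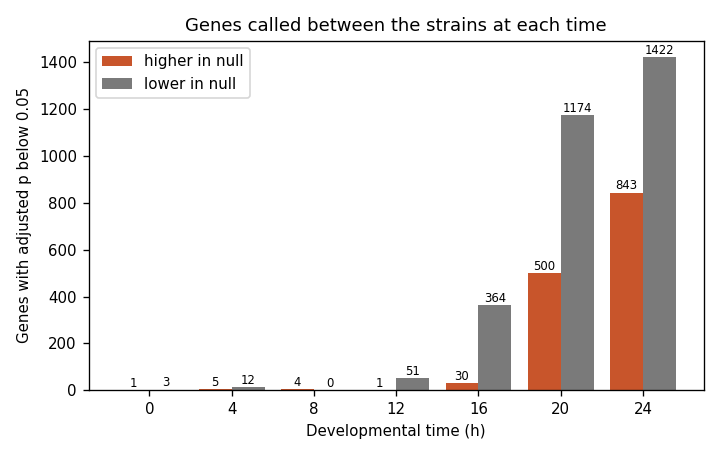
Number of genes called at each time (h) by edgeR, with bars for genes higher and lower in the null strain. At 24 h 843 were higher and 1422 lower with TMM scaling, a split that turned to 2346 higher and 894 lower when libraries were scaled by total counts.

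At 0 h lmcB was higher in the null strain (96.9 ± 60.9 against 1020 ± 362 CPM, n = 2, log2 fold change 3.39, edgeR adjusted p = 0.0059), and the receptor-like gene grlA was lower (log2 fold change -1.42, adjusted p = 0.038). The other 2 called genes have no symbol. These were DDB_G0272030 (log2 fold change -1.43) and DDB_G0282121 (-3.56), named after their values were seen. The count was 2 without wild type 0 h replicate 1 or without null 0 h replicate 2.

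At 4 h lmcB was again higher in the libraries labelled null (23.8 ± 6.67 against 171 ± 79.4 CPM, log2 fold change 2.84, edgeR adjusted p = 0.034). Lower were the GATA factor genes gtaW (105 ± 3.43 against 47.3 ± 4.74 CPM, log2 fold change -1.15, edgeR adjusted p = 0.034), gtaQ (-2.11) and gtaT (-1.36), the chaperonin subunit genes cct3 (-1.33) and cct7 (-1.23), and the actin genes act7 (888 ± 41.1 against 375 ± 4.52 CPM, -1.24) and act2 (-1.36). In all 17 genes differed, 5 higher and 12 lower. Scaling by total counts gave 8 higher and 1 lower, and the deposited RPKM 10 higher and 3 lower. None of the 31 actin genes was higher and 2 were lower (0 and 17 when adjusted over the list alone), with a median log2 fold change of -0.97 (-0.64 with total counts). The list was called by camera (adjusted p = 2.21e-15), and the call held with an estimated correlation (adjusted p = 0.0328), though reads of near-identical actin genes may be shared. None of the 78 ribosomal protein genes was called over all genes, and 34 were lower when adjusted over the list alone (camera adjusted p = 1.24e-32, adjusted p = 0.63 with an estimated correlation). Of 21 GATA factor genes 3 were lower and none higher (camera adjusted p = 0.00434, adjusted p = 0.235 with an estimated correlation). With total counts no gene of the actin, ribosomal or GATA lists was called at 4 h by edgeR, and the GATA median went from -0.311 to -0.0296. After a correction for gene length 5 actin, 7 ribosomal protein and 3 GATA factor genes were lower. The 4 h count rested on single libraries: it was 235 without wild type 4 h replicate 1, 0 without wild type 4 h replicate 2, 0 without null 4 h replicate 1 and 3 without null 4 h replicate 2. Libraries of other times, which inform the spread, moved it too. It was 0 without either wild-type library of 20 h, 4 without either null library of 24 h, and 7 without either wild-type library of 8 h or 12 h or null library of 20 h. It was 8 without either wild-type library of 24 h, 10 without any library of 16 h and 30 without either null library of 12 h.

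At 8 h comH was higher in the null strain (63.4 ± 20 against 224 ± 41 CPM, log2 fold change 1.82, edgeR adjusted p = 0.03). The other 3 called genes, DDB_G0271176 (log2 fold change 6.84), DDB_G0278221 (3.11) and DDB_G0294018 (2.26), were also higher and were named after their values were seen. The count was 0 without any 1 of the 4 libraries of 8 h. It was 1 without either wild-type library of 16 h or null library of 20 h, and 2 without wild type 4 h replicate 2 or any 1 of the null libraries of 16 h, wild-type libraries of 12 h or libraries of 24 h.

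At 12 h 51 genes were lower in the null strain and 1 was higher. Against wild-type values interpolated to the best matching time, 11.6 h, 10 genes differed (1 higher and 9 lower). For many of the 12 h calls a small offset in timing therefore cannot be told from an effect of genotype. hssA, of a family of small proteins, was at 130 ± 58.8 against 5.07 ± 2.61 CPM (n = 2, log2 fold change -4.68, edgeR adjusted p = 0.00012). hssB, of the same family, changed by -3.24 and psiN by -3.09 (95.6 ± 14.1 against 11.2 ± 9.52 CPM, edgeR adjusted p = 0.00085). Also lower were rsc12 (log2 fold change -2.83), mvpB (major vault protein, -1.74), the GATA factor gene gtaJ (45.5 ± 11.1 against 14 ± 5.44 CPM, -1.70), the bZIP factor gene bzpN (202 ± 76 against 70 ± 8.48 CPM, -1.53), efaAII (-1.45), glpV (glycogen phosphorylase, -1.43), taf12 (-1.41) and V4-7 (-1.35). Of 17 prespore markers none was called over all genes, and 4 were lower when adjusted over the list alone (camera adjusted p = 3.33e-05, adjusted p = 0.86 with an estimated correlation). The extracellular matrix list had 5 of 18 lower when adjusted over the list alone (camera adjusted p = 6.93e-05, adjusted p = 0.545 with an estimated correlation). None of 30 heat shock and stress genes was called over all genes, and 6 were higher when adjusted over the list alone (camera adjusted p = 0.00846, adjusted p = 0.943 with an estimated correlation). With total counts no member of these 3 lists was called, and after a correction for gene length 1 prespore marker and 2 matrix genes were lower and 1 heat shock and stress gene was higher. The 12 h count became 149 without wild type 4 h replicate 1, 114 without wild type 4 h replicate 2, 17 without wild type 12 h replicate 2 and 14 without null 12 h replicate 1.

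At 16 h actin and ribosomal protein genes were among those lower in the null strain. The gelation factor gene abpC was at 1510 ± 392 against 304 ± 79.9 CPM (n = 2, log2 fold change -2.31, edgeR adjusted p = 0.0094), alpha-actinin abpA changed by -2.12, and the actin genes act15 by -2.12 (524 ± 82.7 against 121 ± 40.7 CPM) and act16 by -2.08. The ribosomal protein genes rpl3 (1380 ± 134 against 289 ± 30.9 CPM, log2 fold change -2.25, edgeR adjusted p = 0.0013) and rps4 (-2.25) were lower. So were the G protein beta-like gene gpbB (1600 ± 262 against 310 ± 82.8 CPM, -2.37), sdhA (623 ± 126 against 124 ± 31.8 CPM, -2.33), mvpB (-2.35) and ifdA (-2.26). hssA (1590 ± 981 against 98.5 ± 54.5 CPM, -4.01) and the matrix gene ecmF (30.6 ± 25.7 against 2.95 ± 0.0427 CPM, -3.36) had larger changes with a wide spread in the wild type. arrE was higher (17 ± 1.49 against 36.7 ± 14.7 CPM, 1.11, edgeR adjusted p = 0.025), as was the histidine kinase gene dhkJ (1.72). Of 17 prespore markers 2 fell (4 when adjusted over the list alone), the spore coat genes cotA (log2 fold change -1.84) and cotD (-1.58), and camera's adjusted p of 0.00191 became an adjusted p = 0.914 with an estimated correlation. The gene of the protein kinase A catalytic subunit, pkaC, changed by -1.21 (414 ± 3.29 against 179 ± 36.5 CPM) and mybE by -1.17. Of 31 actin genes 10 fell (16 when adjusted over the list alone) and of 78 ribosomal protein genes 17 fell (23 over the list alone). Neither list had a higher gene. Camera's calls of actins (adjusted p = 4.54e-09) and of ribosomal proteins (adjusted p = 2.21e-15) were lost, at adjusted p = 0.1 with an estimated correlation and adjusted p = 0.914 with an estimated correlation. With total counts 1 prespore marker, 7 actin and 13 ribosomal protein genes were lower at 16 h, and after a correction for gene length 3, 11 and 25.

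In all 394 genes were called at 16 h, 364 lower and 30 higher. The percentage lower was 92.4 with TMM, 81.6 with total counts, 81.4 with a correction for gene length and 71.9 with the deposited RPKM. The count fell to 42 without null 16 h replicate 2, to 164 without wild type 16 h replicate 2 and to 210 without null 16 h replicate 1.

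At 20 h, the time of culmination, named spore, stalk and matrix genes were lower in the null strain, some by more than 10 times, and of the lists for them the spore maturation list held its call with an estimated correlation. spiA, a spore coat gene, was at 5650 ± 2500 CPM in the wild type and 36.2 ± 9.59 in the null strain (n = 2, log2 fold change -7.29, edgeR adjusted p = 4.7e-11). The GATA factor gene gtaL was at 417 ± 65.3 against 4.41 ± 2.3 CPM (-6.60, edgeR adjusted p = 3.2e-09), and the matrix gene ecmL at 123 ± 0.39 against 1.8 ± 0.216 (-6.10). The stalk gene staB was at 28.1 ± 3.33 against 0.824 ± 0.0899 (-5.08) and the peroxidase gene poxA at 2150 ± 564 against 56.1 ± 7.8 (-5.26). The sig genes sigD (1220 ± 761 against 8.89 ± 3.25 CPM, -7.12), sigM (-5.39) and sigL-1 (-5.41), pitD (78.3 ± 56.6 against 0.608 ± 0.144) and manD (125 ± 1.08 against 2.86 ± 0.467, -5.45) were also lower. So were aslA-1 (-6.34) and aslD-1 (-6.15, from 4 counts in the null strain), and reads of the genes ending in -1 may be shared with their copies. The prespore surface protein gene pspA was higher (2360 ± 403 against 11000 ± 1090 CPM, 2.21, edgeR adjusted p = 0.00096). Also higher were tpp1 (107 ± 2.79 against 624 ± 109, 2.55, edgeR adjusted p = 0.00011), the cytochrome P450 gene CYP521A1 (55.2 ± 8.94 against 234 ± 70.3, 2.08), psiC (272 ± 83.4 against 1040 ± 222, 1.93) and cmbC (335 ± 1.82 against 1150 ± 263, 1.77). The others were 2C (2.19), alyD-1 (2.38), tspB (2.01), gghB (1.97), hlcs1 (1.87), pks32 (1.75) and prpD (1.73). Reads of 2C may likewise be shared within its family.

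The lists at 20 h are described by how many members rose and fell. Of 15 spore maturation genes none rose and 8 fell (1 and 10 when adjusted over the list alone), among them spiA, sigB (log2 fold change -4.27), sigF (-4.14) and the bZIP factor gene bzpF (418 ± 48.5 against 39.2 ± 16.1 CPM, -3.42). Camera called the list (adjusted p = 1.23e-08), and the call held with an estimated correlation (adjusted p = 0.0328). Of 17 prespore markers 1 rose and 7 fell (1 and 9 over the list alone), with pspA up and cotE (765 ± 444 against 43.5 ± 4.3 CPM, -4.14) and tgrM2 (-2.71) down (camera adjusted p = 0.0058, adjusted p = 0.914 with an estimated correlation). Of 26 prestalk and stalk markers 1 rose and 6 fell, the same numbers as over the list alone, and the list was not called (camera adjusted p = 0.345). They included ecmB (4490 ± 810 against 1050 ± 81.5 CPM, -2.10), ecmF (-3.83) and staA (-5.99, from 2 counts in the null strain, a fitted value that depends on the prior count), whereas ecmA was at 2070 ± 169 against 2450 ± 299 (0.25, edgeR adjusted p = 0.76). With total counts 5 prestalk and stalk markers rose and 6 fell. Of 18 extracellular matrix genes 1 rose and 6 fell (1 and 7 over the list alone), with expl7 at 5040 ± 510 against 788 ± 181 CPM (-2.68; camera adjusted p = 0.0276, adjusted p = 0.914 with an estimated correlation). Of 18 terminal signalling genes 6 fell and none rose (1 rose and 6 fell over the list alone; camera adjusted p = 0.253), among them acgA, an adenylyl cyclase gene of spores, and pkaC (782 ± 33.4 against 403 ± 37.4 CPM, -0.96). Of 21 Myb and other cell-type factor genes none rose and 5 fell (2 and 5 over the list alone), with the MADS-box factor gene srfA at 1300 ± 189 against 339 ± 21.8 CPM (-1.94) and mybE at 2070 ± 124 against 373 ± 4.89 (-2.47). That list was not called (camera adjusted p = 0.424). With total counts Myb and other factors had 2 higher and 3 lower, terminal signalling genes 2 and 3, spore maturation genes 1 and 8, prespore markers 1 and 4, and extracellular matrix genes 3 and 6.

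Among enzyme families at 20 h the polyketide synthases had 5 of 34 higher and 9 lower (6 and 11 when adjusted over the list alone), with pks25 at 248 ± 10.5 against 9.45 ± 1.32 CPM (log2 fold change -4.70). The cytochromes P450 had 5 of 40 higher and 6 lower (7 and 8 over the list alone), the ABC transporters 6 of 65 higher and 4 lower (6 and 4 over the list alone), and the histidine kinases none of 12 higher and 5 lower (1 and 5 over the list alone). These 4 lists were not called (camera adjusted p = 0.237, 0.736, 0.494 and 0.0715). With total counts they had 8 higher and 7 lower, 8 and 5, 18 and 2, and 2 and 3. Of 78 ribosomal protein genes 13 fell and none rose (14 and 0 over the list alone; camera adjusted p = 0.0314, adjusted p = 0.957 with an estimated correlation), with a median log2 fold change of -0.249 that turned to 0.134 with total counts. Of 31 actin genes 8 fell and none rose (11 fell and 1 rose over the list alone; camera adjusted p = 0.0314, adjusted p = 0.914 with an estimated correlation); with total counts 7 fell and 2 rose. The lists not yet described were not called by camera at 20 h either. Their counts are given as higher and lower members, followed by those adjusted over the list alone. GATA factors had 2 and 2 of 21 (2 and 2), bZIP factors 0 and 1 of 17 (0 and 1), and DIF-1 metabolism 0 and 1 of 13 (1 and 2). Aggregation had 0 and 2 of 21 (0 and 1), and growth phase markers 0 and 3 of 18 (0 and 3). Autophagy had 0 and 2 of 13 (2 and 2), proteasome subunits 0 and 1 of 40 (0 and 0), and tgr genes 0 and 3 of 33 (0 and 3). The psi genes had 3 and 2 of 19 (3 and 2), heat shock and stress 1 and 2 of 30 (0 and 0), cell cycle 2 and 2 of 17 (2 and 2), and histones 0 and 0 of 12 (0 and 0). With total counts the direction turned for aggregation (8 higher and 1 lower), growth phase markers (4 and 0), bZIP factors (4 and 1), DIF-1 metabolism (2 and 1), autophagy (3 and 2), proteasome subunits (1 and 0) and heat shock and stress (1 and 0). By the same scaling GATA factors had 2 higher and 1 lower, tgr genes 2 and 3, psi genes 3 and 0, cell cycle genes 2 and 1, and histones 2 and 0. After a correction for gene length aggregation had 5 higher and 2 lower, ABC transporters 12 and 7, autophagy 3 and 2, DIF-1 metabolism 1 and 3, growth phase markers 0 and 5, ribosomal proteins 0 and 20, and psi genes 3 and 3. By the same correction polyketide synthases had 5 and 12, cytochromes P450 7 and 7, histidine kinases 1 and 6, tgr genes 1 and 4, bZIP factors 1 and 1, and heat shock and stress 1 and 3.

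In all 1674 genes were called at 20 h, 500 higher and 1174 lower, of which 20 and 246 differed by at least 10 times. The direction of the whole set depended on scaling, with 70.1% lower by TMM, 60.7% after a correction for gene length, 32.4% by the deposited RPKM and 31.5% by total counts. Total counts moved the median log2 fold change of all genes to 0.41 at 20 h and at 24 h. Without wild type 20 h replicate 2 the count was 979, without null 20 h replicate 1 1017 and without null 20 h replicate 2 1004.

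**Figure D3:**
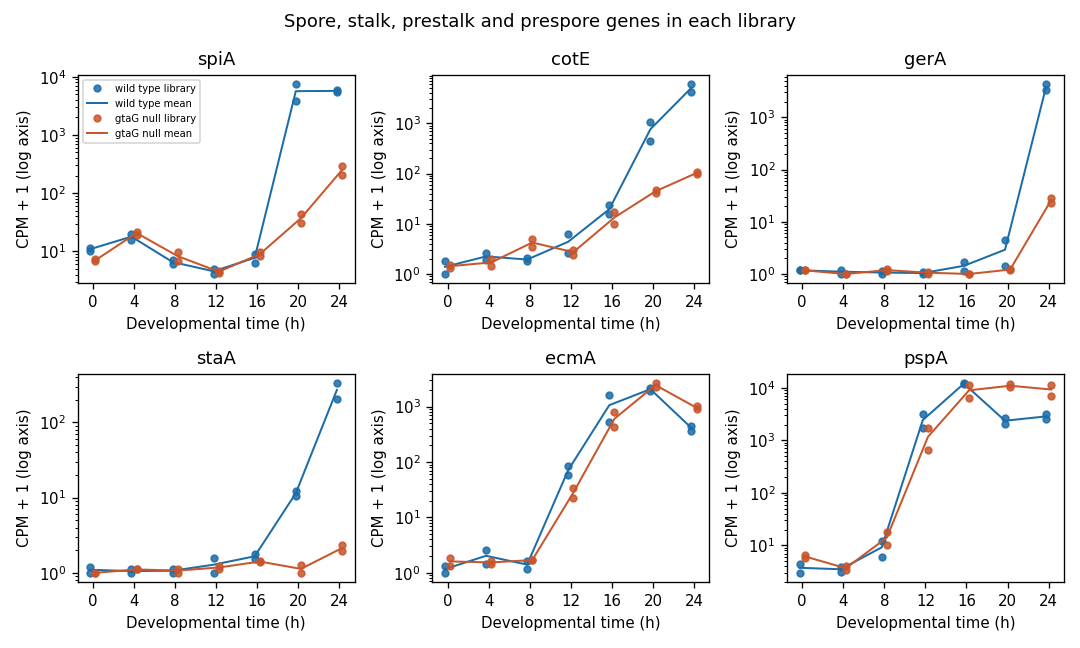
Spore genes spiA, cotE and gerA, the stalk gene staA, the prestalk gene ecmA and the prespore gene pspA (CPM + 1, log axis) against developmental time (h), with points for libraries and lines for means. spiA reached 5650 CPM in the wild type and 36.2 in the null strain at 20 h, whereas pspA stayed at 11000 CPM in the null strain.

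At 24 h, when wild-type fruiting bodies are complete, genes of spore germination, spore coat and stalk were among those with the largest differences. gerA, gerB and gerC, named for spore germination, were at 3830 ± 649, 1570 ± 220 and 3280 ± 318 CPM in the wild type and 25 ± 4.06, 13.4 and 28.7 in the null strain (n = 2). Their log2 fold changes were -7.26, -6.88 and -6.84 (edgeR adjusted p = 8.4e-10, 3.1e-09 and 7.6e-11). The stalk gene staA was at 269 ± 89.4 against 1.13 ± 0.288 CPM (-7.88, edgeR adjusted p = 7.9e-10), the spore coat gene cotE at 5140 ± 1240 against 102 ± 4.09 (-5.65). The matrix gene ecmL was at 1540 ± 497 against 31.4 ± 6.84 (-5.61) and celA, a cellulase of germinating spores, at 751 ± 149 against 18.5 ± 4.53 (-5.35). The annexin gene nxnB was at 66.4 ± 9.59 CPM in the wild type with 3 counts in the null strain, a ratio of 319 with a counting interval from 109 to 1550. ponF (2510 ± 592 against 23.3 ± 3.91 CPM, -6.75), the translation initiation factor gene eIF4e3 (252 ± 1.06 against 3.35 ± 1.35, -6.24), aslH (-6.58, from 4 counts in the null strain) and pitD (-5.24) were lower as well. Higher in the null strain were pks32 (7.19 ± 1.92 against 44.2 ± 11.8 CPM, 2.63), pks30 (2.28), the cAMP receptor gene carB (29.5 ± 2.8 against 105 ± 21.2, 1.83, edgeR adjusted p = 7.4e-05), ecmD (277 ± 61.8 against 1010 ± 148, 1.86, edgeR adjusted p = 9.3e-05) and CYP521A1 (1.94). Also higher were orcE (2.10), lrlA (2.19), 2C (2.14), tgrG1 (1.86), tgrD1 (1.73), pyr4 (1.73) and abcG17-1 (2.33). The null libraries were far apart for abcG17-1 (96.2 ± 79.7 CPM), and reads of it and of 2C may be shared with close copies.

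Of 15 spore maturation genes 1 rose and 9 fell at 24 h, the same numbers as when adjusted over the list alone (median log2 fold change -2.25). spiA was among those that fell (5720 ± 396 against 249 ± 64.5 CPM, -4.52). Camera called the list (adjusted p = 1.55e-06), and the call held with an estimated correlation (adjusted p = 0.0455); with total counts 3 rose and 8 fell. All 10 tested sig genes fell with TMM scaling (camera adjusted p = 7.44e-11 over 720 tests of 90 symbol families, adjusted p = 0.0903 with an estimated correlation). Of these sigB, sigD, sigE and sigF are also in the spore maturation list. The spore germination list, too small for a list test, held 4 tested genes, without gerA, gerB and gerC. Of them 2 fell and none rose (2 and 0 over the list alone), celA and celB (681 ± 196 against 27.9 ± 8.35 CPM, -4.61). Both are also in the spore maturation list. Of 17 prespore markers 1 rose and 4 fell (1 and 4 over the list alone; camera adjusted p = 0.136; 1 and 3 with total counts), and the abundant coat genes cotB at 4060 ± 56.8 against 5760 ± 1710 CPM (0.51, edgeR adjusted p = 0.46) and cotC at 6800 ± 300 against 8220 ± 2820 (0.27, edgeR adjusted p = 0.77) did not pass. Of 26 prestalk and stalk markers 6 rose and 6 fell (6 and 7 over the list alone; camera adjusted p = 0.74), with ecmA at 410 ± 59.7 against 951 ± 87.7 CPM (1.21, edgeR adjusted p = 0.043), ecmB at 1650 ± 233 against 429 ± 161 (-1.94) and staB at 96.1 ± 1.52 against 11.6 ± 2.3 (-3.05). With total counts 8 of them rose and 5 fell. Of 18 extracellular matrix genes 4 rose and 8 fell (4 and 8 over the list alone), with expl2 at 1500 ± 172 against 46.4 ± 9.71 CPM (-5.01; camera adjusted p = 0.0408, adjusted p = 0.914 with an estimated correlation).

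Of 78 ribosomal protein genes 40 fell and none rose at 24 h (52 and 0 when adjusted over the list alone), with rpl5 at 2130 ± 326 against 619 ± 72.9 CPM (log2 fold change -1.78), rpl7a (-1.58) and rplP0 (-1.52). Fold changes at 24 h followed gene length across genes (Spearman rho 0.196), and ribosomal protein genes are short (median 784.5 bases against 1522). This trend was not particular to 24 h, since rho ranged from -0.133 at 16 h to 0.417 at 0 h. The median was -1.04 by TMM (camera adjusted p = 3.86e-13, adjusted p = 0.914 with an estimated correlation), -0.635 by total counts and -0.867 after a correction for gene length. Total counts left 28 genes lower and the length correction 55, with none higher in either. Of 31 actin genes 12 fell and none rose (13 and 1 over the list alone; camera adjusted p = 0.0468, adjusted p = 0.914 with an estimated correlation), and with total counts 10 fell and 4 rose. Of 65 ABC transporters 12 rose and 4 fell (13 and 4 over the list alone; camera adjusted p = 0.0408, adjusted p = 0.957 with an estimated correlation). Of 21 GATA factor genes 6 fell and none rose (6 and 0 over the list alone; camera adjusted p = 0.254), with gtaE at 107 ± 2.34 against 16.6 ± 5.77 CPM (-2.69) and gtaL (-4.06), and with total counts 4 fell and 2 rose. The ABC transporters had 22 higher and 1 lower with total counts, and 14 higher and 10 lower after the length correction. With total counts the extracellular matrix list had 6 higher and 7 lower. The lists that follow were not called by camera at 24 h either. Of 18 terminal signalling genes 2 rose and 2 fell (3 and 2 over the list alone), with the histidine kinase gene dhkA at 171 ± 49.8 against 361 ± 64 CPM (1.08). Of 12 histidine kinases 3 rose and 3 fell (3 and 3), with dhkJ at 157 ± 51.1 against 5.76 ± 2.14 CPM (-4.77). Of 34 polyketide synthases 8 rose and 9 fell (9 and 10), of 40 cytochromes P450 11 and 6 (11 and 7), and of 33 tgr genes 4 and 4 (5 and 6). Of 19 psi genes 2 rose and 4 fell (2 and 4), and of 17 bZIP factors 2 and 1 (2 and 1). Of 21 Myb and other factors 2 rose and 4 fell (2 and 4), of 13 DIF-1 genes 1 and 2 (1 and 2), and of 21 aggregation genes 2 and 2 (3 and 2). Of 18 growth phase markers 0 rose and 5 fell (0 and 6), and of 13 autophagy genes 1 and 2 (1 and 2). Of 40 proteasome subunits 0 rose and 3 fell (0 and 2), with psmF1 at 157 ± 0.571 against 37.9 ± 3.16 CPM (-2.05). Of 30 heat shock and stress genes 1 rose and 2 fell (1 and 2), of 17 cell cycle genes 0 and 1 (0 and 1), and of 12 histones 0 and 1 (0 and 1). The counts of these lists depended on scaling and on gene length. With total counts aggregation genes had 9 higher and 1 lower, heat shock and stress 8 and 2, tgr genes 6 and 1, autophagy genes 6 and 0, terminal signalling 5 and 1, psi genes 5 and 3, and proteasome subunits 2 and 2. Polyketide synthases had 10 and 8, cytochromes P450 14 and 6, histidine kinases 3 and 2, bZIP factors 3 and 1, growth phase markers 0 and 3, and histones 1 and 1. By the same scaling 4 Myb and other factors rose and 3 fell, 3 DIF-1 genes rose and 1 fell, and 2 cell cycle genes rose and 1 fell. After the length correction terminal signalling had 4 higher and 5 lower, histidine kinases 3 and 6, proteasome subunits 1 and 6, DIF-1 genes 3 and 4, psi genes 3 and 4, and polyketide synthases 7 and 10. By the same correction aggregation genes had 5 and 2, autophagy genes 4 and 2, heat shock and stress 4 and 3, cytochromes P450 13 and 6, and growth phase markers 0 and 6. The bZIP factors had 3 and 3, Myb and other factors 4 and 4, tgr genes 5 and 5, GATA factors 1 and 6, and cell cycle genes and histones 0 and 1 each. The list for the hssA/2C/7E family, matched by symbol, held hssA alone, which was lower at 24 h (log2 fold change -1.91). It missed hssB and 2C, so it gives no direction for the family. None of the 4 tested colossin genes was called by edgeR at any time or when adjusted over the list alone at 24 h, and 2 were higher over the list alone at 20 h. No member of the mitochondrial or non-coding lists was matched in the files.

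In all 2265 genes were called at 24 h, 843 higher and 1422 lower. Of the called genes 62.8% were lower by TMM, 53.1% after a correction for gene length, 27.6% by total counts and 26.9% by the deposited RPKM. The count was 1336 without wild type 24 h replicate 1 and 1374 without null 24 h replicate 1.

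The late change from 16 h to 24 h was compared within and between the strains, to ask whether the null strain passed through the terminal phase. In the wild type gerC went from 2.42 ± 0.0942 to 3280 ± 318 CPM, cotE from 18.6 ± 5.63 to 5140 ± 1240 and celA from 6.57 ± 0.0123 to 751 ± 149. In the null strain they went from 3.09 ± 0.154 to 28.7 ± 6.72, 12.4 ± 5.11 to 102 ± 4.09 and 6.82 ± 3.13 to 18.5 ± 4.53. pspA went from 12000 ± 377 to 2860 ± 429 CPM in the wild type and from 8960 ± 3630 to 9280 ± 3050 in the null strain. For ecmA the means were 1060 ± 758 and 410 ± 59.7 CPM in the wild type and 604 ± 255 and 951 ± 87.7 in the null strain. The wild-type libraries of 16 h stood at 525.9 and 1598 CPM, and the call of its late difference (2.03, edgeR adjusted p = 0.047) was lost in 25 alternatives. The change was called for 3074 genes in the wild type (1642 up and 1432 down, 452 and 86 by at least 10 times) and 1542 in the null strain (851 up and 691 down, 177 and 35). It differed between the strains for 567 genes, 438 with a smaller rise or a larger fall in the null strain and 129 the other way. The percentage on the first side was 77.2 by TMM, 66.4 by total counts and 67.3 by the deposited RPKM, and of the late changes in the null strain 44.8% were down by TMM and 35.8% by total counts. Among 683 genes chosen by a rise of at least 4 times in wild-type replicate 1, the median log2 change was 3.09 in wild-type replicate 2 and 1.06 and 1.20 in the null replicates. Chosen in replicate 2 (594 genes), it was 4.09 in replicate 1 and 1.14 and 1.29 in the null replicates. The null count was 883 without null 16 h replicate 1, 989 without null 16 h replicate 2 and 774 without null 24 h replicate 2, and the count of differing genes was 363 without null 16 h replicate 2 and 360 without wild type 24 h replicate 1.

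Libraries were also compared as a whole by Spearman correlation over genes regulated in wild-type development. Each null library up to 16 h correlated best with wild-type libraries of its own time (0.9724 or more). The null libraries of 20 h correlated best with the wild type at 16 h (0.9542 and 0.9484, against 0.9221 and 0.9244 at their own time). Those of 24 h also correlated best with the wild type at 16 h (0.9223 and 0.9142, against 0.8988 and 0.9074 at their own time), but the wild type at 20 h was close (0.9099 and 0.9114), and with the deposited RPKM null 24 h replicate 2 correlated best with 24 h (0.9031). The first 3 principal components held 62.1%, 14.1% and 7.6% of the variance.

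**Figure D4:**
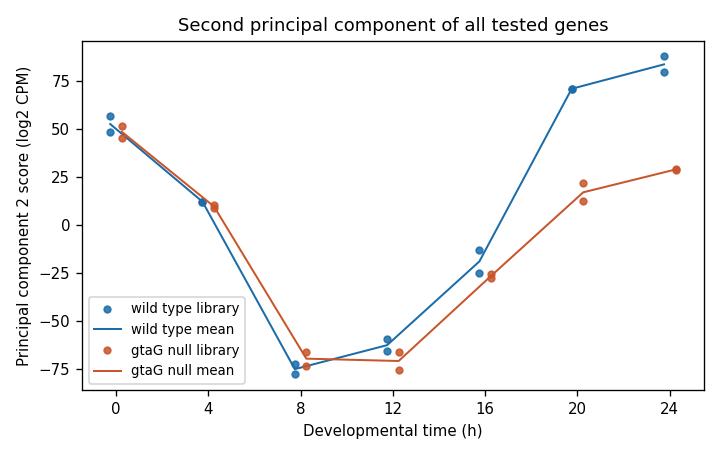
Score of each library on principal component 2 of all tested genes (log2 CPM, 14.1% of the variance) against developmental time (h), with lines for the strains' means. The wild-type libraries of 24 h sit at 87.93 and 79.71 and the null libraries at 28.56 and 29.39.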

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

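The tests of wild-type RNA and of a fixed part of gtaG, with and without 4 h, were chosen only after the results they address were seen, the gene length correction was added after the trend between replicates was seen, and the shared-delay test was added once the result of the slower-course test was known.

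The genotype effect on the late change from 16 h to 24 h was singled out because the strains' changes differed by a test of the difference itself, for 567 genes (129 and 438 in each direction with TMM). Among the genes that fell less or rose more in the null strain, the difference of the log2 changes was 2.93 for abcG17-1, 2.58 for 2C, 2.41 for rasX, 2.31 for pks32, 2.23 for adamts and 2.15 for pks30. It was 2.13 for pspA, 2.03 for ecmA, 1.88 for pyr4, 1.87 for ubqH, 1.87 for sir2B and 1.78 for cryS. Among those that rose in the wild type and rose less or did not rise in the null strain it was -7.21 for staA, -7.19 for gerC, -6.49 for dhkJ, -6.37 for eIF4e3, -6.28 for ponF and -5.66 for pks13. It was -5.40 for celA, -5.22 for aslH and -5.07 for cotE. The fitted values of -7.42 for dhkF, -6.07 for ubqO and -5.66 for aslD-1 rest on 1, 1 and 3 counts in the wild type at 16 h and depend on the prior count. Those for staA, pks13 and aslH rest on few counts too, with 8, 5 and 13 in the wild type at 16 h. In the null strain at 24 h these genes had 16, 17 and 4 counts. By edgeR the adjusted p ranged from 1e-07 for gerC to 0.047 for ecmA. The null libraries of 24 h were far apart for abcG17-1 (96.2 ± 79.7 CPM). Reads of 2C and of the genes ending in -1 may be shared with close copies. The late calls for 2C and pspA no longer passed in 15 alternatives each.

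The spore maturation list had a median difference in late change of -2.31 (0 genes higher and 8 lower over all genes by edgeR, 1 and 8 adjusted over the list alone). Camera's adjusted p was 1.8e-06 and held with an estimated correlation (adjusted p = 0.0455). The ribosomal protein list had a median of -0.494 with no gene called in either direction by edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.957 with an estimated correlation).

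The genotype effect on gtaG reads differed between times, by 5.39 on the log2 scale between 4 h and 12 h (edgeR adjusted p = 0.00087) and by 4.53 between 4 h and 24 h (edgeR adjusted p = 0.00011). Wild-type RNA in the null libraries would bring every wild-type transcript, but 257 of 5084 genes at 20 CPM or more in the wild type at 24 h lay below 15.3%, which is 0.5 of the gtaG ratio of 30.6%, in both null libraries. A remaining part of the gene, read under unchanged control, would keep the ratio equal at 4 h and 12 h, which the difference of 5.39 excludes only if the 4 h labels hold. With 4 h left aside it stays open: equal effects at the 6 other times gave an edgeR p of 0.0098 (adjusted p = 0.078), 0.024 without 0 h (adjusted p = 0.15), where libraries held 3 to 7 counts, and effects at 12 h and 24 h differed by -0.865 (edgeR adjusted p = 0.42). Altered control of a remaining part and labels exchanged at 4 h alone were not tested, nor was a biological explanation. Yet lmcB, a single gene, was higher under the null label at both 0 h (96.9 against 1020 CPM) and 4 h (23.8 against 171). The share of counts on unmatched identifiers was higher in each null library than in the same-numbered wild-type library at all 7 times. At 4 h it was 0.824% and 1.49% against 0.513% and 0.655%. At 0 h wild type replicate 2 (1.02%) exceeded null replicate 1 (0.958%). Both measures argue against an exchange at 4 h without excluding it.

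The number of genes differing between the strains at any time, 2253, was weighed against chance, gene length and depth. Of 100 splits of the libraries within each time, the real one included, 4 gave as many called genes, and the highest other gave 3042. The share was just under 0.05, but it is no plain measure of chance, since splits could keep the real labels at some times. The 3 splits with more than 2253 (3042, 2553 and 2355) kept the real labels at 20 h and 24 h. They followed replicate number at 3, 2 and 4 other times, and a fit with replicate number as a block gave 3485. Splits with other labels at 24 h gave at most 54 genes, and those with other labels at 20 h as well gave 0. Such splits put libraries of both strains into a group, which widens the spread that all groups share. Their low counts were thus partly built in and do not show what chance alone would give. At 24 h 98.3% of the calls stayed in the same direction after a correction for gene length, and 93.6% with every library thinned to 5429366 counts, which argues against a length trend or depth as the whole cause. The difference in strain that the design names stays open, as untested apart from the comparison itself.

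The null libraries of 20 h and 24 h correlated best with the wild type at 16 h. A slower or mixed course through the wild-type stages would leave few genes outside the range of the 7 wild-type times, and 0.132% of the genes called at 24 h lay outside (3 genes), which is consistent with it, though at 16 h 3.81% did (15 of 394, 14 of them below every wild-type time) and the test has low power since a gene must pass every wild-type time. A delay shared by all genes would leave few genes away from the best interpolated wild-type time. For the null strain at 24 h that time was 17.6 h, and 23.8% of the tested genes differed from it (1156 higher and 1411 lower). At 20 h 5.01% differed (540 genes, against 1674 called between the strains at 20 h), with a best time of 17.8 h. At 16 h, where the null libraries correlated best with their own time, 3.91% differed from the best time of 15.2 h. The 20 h value was close to that level and does not argue against a delay. The 24 h value argues against a delay as straight lines between log2 values of neighbouring times describe it. It does not exclude one, since no wild-type time was held out to show how well such lines hold. A loss of one part of the late program, with the rest continuing, stays open and was not tested separately. A difference between cell types in their progress stays open too.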

How the results depend on the processing

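The correction for gene length and the fit to the 16 h and 20 h libraries alone were chosen after seeing the data. Alternatives were compared for 107 values of 85 genes named for the largest fold changes. Genes named only as list members, and gtaG at times other than 12 h, are not among them. Of 4232 alternative values, 3857 kept their direction and side of the threshold, 371 kept their direction but no longer passed, and 4 reversed. Those that reversed were the late differences with 20 h in place of 16 h, for pspA (-0.515), ubqO (1.13) and aslD-1 (0.927), and the value of 2C, late change by genotype, which became -0.0513, where the early time itself had changed. The uncalled gtaG value at 0 h ranged from -0.0159 without null 0 h replicate 1 to 1.19 without null 0 h replicate 2. Among the 107 values, calls lost most often were gtaT and cct7 at 4 h (29 each), cct3 at 4 h (28), ecmA in the late change (25), grlA at 0 h (24) and efaAII at 12 h (20). The call for gtaG at 16 h, often lost as described above, is outside this ranking.

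Counts of genes moved by over 1.5 times as follows, and the cause was not tested unless stated. DESeq2 gave 17 genes at 0 h, 191 at 4 h, 15 at 8 h and 234 at 12 h. An additive replicate block gave 17, 210, 9, 273 and 657 from 0 h to 16 h, 3485 at any time and 927 in the late difference, and same-numbered libraries of the strains deviated together at 0, 4, 8, 12 and 24 h (correlations from 0.389 to 0.559) but not at 16 h (-0.117) or 20 h (0.0143), so the numbers were not taken as pairs. A block within each genotype gave 13, 80 and 13 at 0 h, 4 h and 8 h and 919 in the late difference. The length correction gave 8, 88 and 210 at 0 h, 4 h and 12 h, 3498 at any time and 873 in the late difference. The deposited RPKM gave 10 at 0 h, 2544 at 20 h, 3451 at 24 h, 3541 at any time and 865 in the late difference. Total counts gave 9 at 4 h and 239 at 16 h, RLE scaling 2 at 8 h, and the stricter filter 11 at 4 h and 0 at 8 h. Fits to the 4 libraries of a time alone, with fewer samples, gave 0, 0, 0, 3 and 2716 at 0, 4, 8, 12 and 20 h, and the fit to 16 h and 20 h gave 745 at 16 h. The single-time fits gave 539 at 16 h and 2011 at 24 h, within 1.5 times, so by them fewer genes differed at 24 h than at 20 h. An adjusted p under 0.01, a stricter threshold, gave 0, 0, 24, 182, 1015 and 1371 at 4, 8, 12, 16, 20 and 24 h, 1402 at any time, 908 in the late change of the null strain and 312 in the late difference. With 20 h in place of 16 h the late change held 1605 genes in the wild type, 996 in the null strain and 268 in the difference, and with 12 h 4402 in the null strain. Of 49 list calls, 4 held in number with an estimated correlation and fry gave 19. Among values other than counts of genes, the median log2 change of late-induced genes in the null strain, 1.17, became 0.647 at a rise of 2 times, 1.58 at 8 times and 0.85 with a pseudocount of 5. The 4 late null libraries that best matched an earlier wild-type time became 3 with the deposited RPKM, a smaller move.

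Leaving out a library gave from 2 to 6 genes at 0 h, 0 to 235 at 4 h, 0 to 5 at 8 h, 14 to 149 at 12 h, 42 to 476 at 16 h, 979 to 1771 at 20 h and 1336 to 2404 at 24 h. It gave 1796 to 2414 at any time, 2056 to 3169, 774 to 1649 and 360 to 612 in the late change of the wild type, of the null strain and in their difference, 9656 to 9978 in development, and 42 to 53 list calls. The gtaG value at 24 h ranged from -1.79 to -1.64. A group left with 1 library was assumed to vary like the others. Depth limited genes with few counts, where fitted values depend on the prior count.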

Other observations

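The interpolation between wild-type times was chosen after the correlations between libraries were seen. Families sharing a symbol stem held some groups outside the lists. Of 12 osb genes, named for oxysterol binding, none was higher and 7 were lower at 20 h with TMM, and 1 higher and 7 lower at 24 h. Adjusted over the list alone the numbers were 2 and 9 at 20 h and 1 and 8 at 24 h (camera adjusted p = 0.00108 and 0.00298, adjusted p = 0.516 and 0.652 with an estimated correlation). In the late change 1 osb gene was higher and 6 were lower. Of 27 eIF translation factor genes none was higher and 8 were lower at 24 h with TMM (camera adjusted p = 0.0428, adjusted p = 0.995 with an estimated correlation). Of 8 vat genes, named for the vacuolar proton pump, 2 were higher and none lower at 20 h (camera adjusted p = 0.0427, adjusted p = 0.995 with an estimated correlation). None of the 720 family tests was called by camera with an estimated correlation, and 59 were called with the preset one.

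The 10 sig genes, some of them also in the spore maturation list, had a median late difference of -2.99. All 10 were lower in the null strain (camera adjusted p = 4.92e-14, adjusted p = 0.0864 with an estimated correlation). At 24 h efa1B stood at 179 CPM in the null strain against 545 in the lowest wild-type time and vwkA at 12.5 against 32.1, while DDB_G0271176 stood at 11.7 against 0.979 in the highest. Against interpolated wild-type times the null libraries of 0 to 16 h matched best at 0.4, 4.2, 7.8, 11.6 and 15.2 h. From these times 13, 16, 4, 10 and 421 genes differed.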
